A study of Mus musculus with 18 samples.

How the data were processed

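RNA was measured in mouse uterus, eutopic endometrium and ectopic endometriotic lesions of 2 genotypes. These were ERBOE, described as overexpressing oestrogen receptor beta, and PRCre, the Cre driver line that served as control. Each of the 18 samples was total RNA pooled from 3 animals, and 3 such pools from 9 animals formed each of the 6 groups. Ectopic lesions came from ERBOE or PRCre endometrial fragments, punched at 2 mm, that had been implanted in wild-type hosts of 8 weeks of age. Eutopic endometrium came from ERBOE or PRCre hosts that carried a wild-type implant, so by this account the lesions and the eutopic samples were from different animals. The labels leave a doubt: the source field of the ERBOE lesion and eutopic samples calls those mice free of endometriosis, against the titles, and the account of the eutopic samples has lesions collected before it has eutopic endometria pooled. Titles and the rest of the account were followed. Both were collected at estrus 4 weeks after surgery. Uterus came at estrus from mice of 12 weeks without surgery.

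Labelled cRNA, 600 ng per sample made from 25 ng of total RNA, was hybridised by the authors to 1-colour Agilent mouse arrays whose grid was built on mm9. The deposited scanner files hold spot intensity (processed, median and local background signal) that the authors' scanner software had background-subtracted and detrended but not normalised between arrays. The deposited value table holds log2 values that are centred per probe across arrays and behave as 75th percentile scaled signals, with a correlation of 0.9986 to 0.9994 with centred scanner values over the 18 arrays. How that table was made is not given in the sources used here.

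The analysis started from the processed intensity. Control spots and spots called outliers by the scanner software were left out, the log2 intensity was taken, each array's 75th percentile was subtracted, and spots of 1 probe were averaged. A probe was kept if its signal was well above background on at least 3 of the 18 arrays. Probes were named through the RefSeq gene table of assembly GRCm38.p6, which gave 32994 of 56605 probes a symbol. The brightest probe stood for each of 22911 symbols, and probes without a symbol were tested under their own identifiers, for 33185 features tested, 17908 of them with a symbol.

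The depth of each array was read as its 75th percentile signal, its share of probes well above background and its saturated spots. The number of arrays limits the precision. A group in which no array was well above background gives a fold only as a bound, computed from the lowest signal called above background.

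One limma linear model (limma 3.58.1 in R 4.3.3) held the means of the 6 groups over all 18 arrays, with empirical Bayes moderation (residual degrees of freedom 12, prior 2.48) and 2-sided tests. Benjamini-Hochberg adjustment ran over all features of a comparison, with 0.05 as the threshold. The 10 comparisons were ERBOE against PRCre in each tissue, ectopic against eutopic in each genotype, eutopic against uterus in each genotype, and the 3 differences of the genotype effect between tissues. With 3 arrays against 3, a permutation test cannot go below 0.1, so no single-gene permutation p is given. Errors beside differences are limma standard errors, and errors beside group means are standard deviations over 3 arrays. Tests on simulated data added known shifts to 200 of 31560 genes. The model then recovered 5% of genes shifted by 1 log2 unit, 60% at 2 units and 75.5% at 3 units, with at most 8 false calls. The simulated noise was normal and independent between genes, without slide or replicate structure, so these figures need not hold for the real arrays.

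The 32 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and fry as checks. They cover oestrogen-induced and progesterone-induced uterine genes, E2F and cell-cycle genes, TNF and NF-kB response genes, inflammasome, apoptosis, interferon response, complement, matrix and EMT, endothelial and angiogenesis, steroid and prostaglandin synthesis, hypoxia and glycolysis, neural, and immediate-early genes, and markers of NK and cytotoxic lymphocytes, T cells, B and plasma cells, macrophages, neutrophils, eosinophils and mast cells, epithelium, glands, ciliated cells, endometrial stroma, smooth muscle, mesothelium, adipocytes, skeletal muscle, ovary and oviduct, intestine and pancreas, erythroid cells and squamous keratinocytes. A list is called when its camera adjusted p at the preset correlation is under the threshold.

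The groups, the comparisons, the lists, the tests, the filter, the alternatives and the rule for naming genes were fixed before the data were examined. That rule names Esr2, Esr1 and Pgr always. For a genotype comparison it names up to 10 genes each way among those past the threshold with groups that do not overlap, or the 10 smallest p if fewer than 10 pass. For other pairwise comparisons it takes 5 each way, and for a described list up to 4 members with the smallest p. Which lists are described in full, the contrasts pooled over tissues or genotypes, the count of features shared by 3 tissues and the run of all comparisons without PRCre uterus replicate 1 were chosen after seeing the data.

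Alternatives were normexp background correction with an offset of 50, quantile normalisation, median centring, the deposited value table, no filter, a filter requiring all 18 arrays, the mean of all probes of a gene, slide as a block, the replicate number as a block, trended and robust variance, array weights, a fit of the compared arrays alone, and leaving out each array. The normexp step used median signals, since the files analysed here carry no mean signals. The arrays lay on 3 slides, which do not hold every group. Array deviations from the group means correlated between arrays of the same replicate number at 0.404, 0.313 and 0.449 for PRCre and ERBOE uterus, whose numbers coincide with the slides. They correlated at 0.345, 0.233 and 0.138 for PRCre lesions and PRCre eutopic endometrium, which lay on different slides. The numbers were therefore taken to pair those arrays, a reading from the data, since what a number marks is not given in the sources used here. That reading is weak for the PRCre lesion and eutopic arrays. Arrays of unlike number reached 0.325, 0.301 and 0.241 for PRCre eutopic endometrium and uterus. Splits that part these pairs were added after seeing the data. Correlations of genotype effects are across genes, which are not independent replicates, so they carry no p. Plots and tables used numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.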

Results

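Gene expression was measured on 18 one-colour arrays, 3 for each of 6 groups. The groups were uterus, eutopic endometrium and ectopic lesions of PRCre control mice and of ERBOE mice, described as overexpressing oestrogen receptor beta. Each array carried RNA pooled from 3 animals. The 75th percentile signal ranged from 455.1 to 744.7 on 17 arrays and was 239.6 on PRCre uterus replicate 1. Between 55.3% and 74.2% of probes were well above background, and 0 spots were saturated. Arrays correlated with each other at 0.916 to 0.978, with a median of 0.956 within groups, and the first principal component held 18.9% of the variance. Slide 1 held no eutopic array and slide 3 held no PRCre ectopic array, so only the uterus comparison had both groups on all 3 slides.

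Esr2, which encodes oestrogen receptor beta, was read at a similar level in every group by its bright probe, with group means between 2.19 and 2.69 log2 units above the array's 75th percentile. The ERBOE minus PRCre difference was -0.24 ± 0.20 (SE, n = 3 arrays per group) in the uterus, 0.01 ± 0.20 in eutopic endometrium and -0.26 ± 0.20 in lesions, and none passed the threshold in limma. With slide as a block these Esr2 differences were -0.24, 0.01 and -0.19. Within the slides that held both genotypes they were -0.11, -0.18 and -0.42 in the uterus, 0.13 and -0.04 in eutopic endometrium, and -0.37 and -0.07 in lesions. The other Esr2 probe was well above background on at most 1 array of any group. Where these probes lie relative to the transgene is not given in the sources used here, so they cannot show or exclude overexpression. Esr1, the gene of oestrogen receptor alpha, differed by 0.06, 0.09 and -0.18 (each ± 0.33) in uterus, eutopic endometrium and lesions. Pgr, the progesterone receptor gene whose locus drives Cre in these mice, differed by -0.27, 0.42 and -0.22 (each ± 0.59). None of the 3 genes passed in the ectopic against eutopic or the eutopic against uterus comparisons either. The largest of those differences were in ERBOE lesions against ERBOE eutopic endometrium, at -0.69 ± 0.33 for Esr1 (adjusted p = 0.48) and -0.96 ± 0.59 for Pgr (adjusted p = 0.624).

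**Figure D1:**
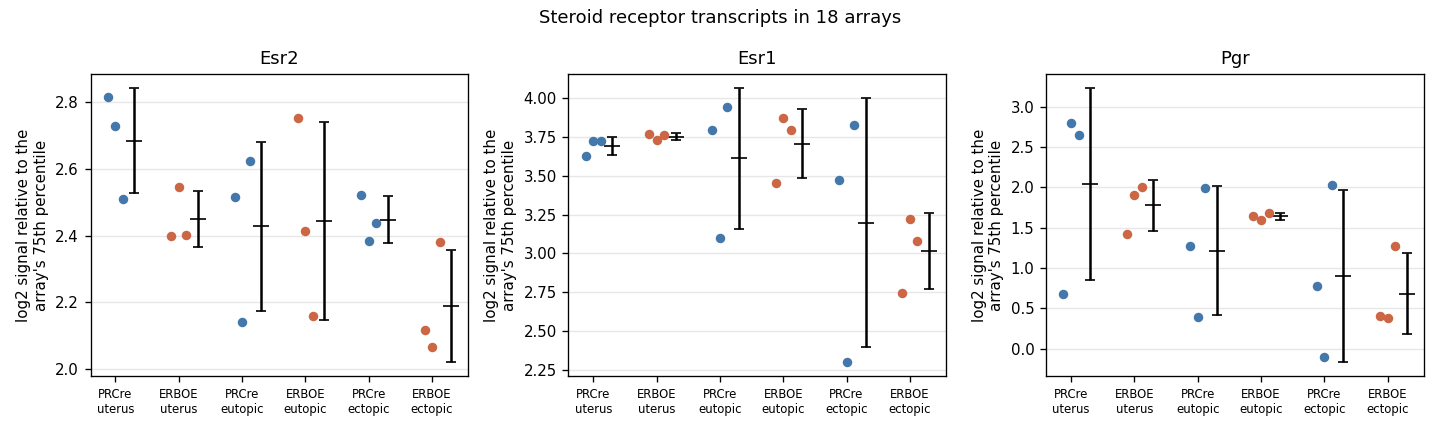
Log2 signal relative to the array's 75th percentile for Esr2, Esr1 and Pgr, with 1 point per array, and a bar for the mean and SD of each of the 6 groups of 3 arrays. Group means of Esr2 lie between 2.19 and 2.69, and Pgr on PRCre uterus replicate 1 lies at 0.67 beside 2.80 and 2.65 on the other 2 arrays of its group.

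The genotype comparison in the uterus asks how ERBOE differs from PRCre in the organ without lesions. Genes of the cell cycle and of the epithelium read higher in ERBOE uterus as groups, and markers of mast cells and natural killer cells read lower, though no list was called with an estimated correlation. Of 47 E2F and cell-cycle genes tested, 47 were higher, with a median log2 difference of 1.1, and Plk1, a mitotic kinase, read 2.37 ± 0.74 higher (unadjusted p = 0.00636). Of 28 epithelial markers, 26 were higher by a median of 1.19, with Cdh1, the gene of E-cadherin, at 1.99 ± 0.56 and the keratin gene Krt19 at 2.40 ± 0.85. No single gene passed in limma, which gave 3280 features at an unadjusted p under 0.05 where 1659 would come by chance, and a smallest adjusted p of 0.0986. Other splits of the same arrays gave as many as 4206 and 4916 such features. The excess over 1659 therefore cannot be credited to genotype alone.

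The genes given here are among those with the smallest p in the uterus, and none passed. They were led by Clvs2, which encodes a lipid-binding protein of clathrin-coated vesicles and read -2.61 ± 0.38 in ERBOE. Tm7sf2, a sterol reductase of cholesterol synthesis, read 1.52 ± 0.24, and Ephx1, which encodes microsomal epoxide hydrolase, 1.25 ± 0.23. Slc16a6, a solute carrier gene, differed by 1.62 and the kinase gene Dyrk3 by 1.28, while Nme4, a mitochondrial nucleoside diphosphate kinase gene, differed by -1.70 and Clec14a, an endothelial surface protein gene, by -1.38. Serpina3n, a serine protease inhibitor gene, and Atp8b5 were not well above background in ERBOE uterus and were measured on 2 of 3 PRCre arrays, at least 4.80-fold and 2.36-fold lower. Adjusted p of the genes given after Clvs2 ran from 0.183 to 0.209. The count of 0 became 3 without PRCre uterus replicate 1 and 2 without PRCre uterus replicate 2, and 9 with array weights, among them Clvs2 and Tm7sf2 (adjusted p = 0.0402 each). The median difference of all features was -0.11 in this comparison, against which the values above can be read.

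In the camera test, 10 of 32 lists were called in the uterus, 5 higher and 5 lower, and 0 of them with an estimated correlation, where the smallest adjusted p was 0.639. Cell-cycle genes had an adjusted p = 5.38e-16 (adjusted p = 0.717 with an estimated correlation) and a median of 1.1 with slide as a block, with 1.63, 1.06 and 0.85 within slides. Epithelial markers had 3.58e-11 (0.717 with an estimated correlation), with a block median of 1.19 and 0.97, 1.38 and 1.16 within slides, and Epcam and Lsr read 1.61 and 1.13. Oestrogen-induced uterine genes were higher for 15 of 21 members (median 0.88; adjusted p = 0.00348; 0.717 with an estimated correlation), with 1.12, 1.31 and 1.06 within slides, Krt7 at 1.61, C3 at 1.56 and the connexin gene Gjb2 at 3.12. Mast cell and eosinophil markers were lower for 13 of 14 members (median -1.16; adjusted p = 0.00117; 0.639 with an estimated correlation; within slides -1.23, -0.66 and -1.51), among them the mast cell proteases Mcpt4 at -1.88 and Cpa3 at -1.92. NK and cytotoxic lymphocyte markers were lower for 22 of 24 members (median -0.95; adjusted p = 0.00348; 0.863 with an estimated correlation; within slides -0.55, -1.03 and -1.19), with Klra9 at -1.08 and Klri2 not well above background in ERBOE and at least 1.46-fold lower, measured on 1 PRCre array. Endothelial genes were lower for 26 of 33 (median -0.50; adjusted p = 0.00915; 0.873 with an estimated correlation), with Ecscr at -1.20, Tek at -1.35 and Vegfd at -1.84 but Esm1, a secreted product of endothelial cells, at 3.09. Their call ended without PRCre uterus replicate 2 (median -0.28, adjusted p = 0.13), PRCre uterus replicate 3 (-0.26, 0.765) or ERBOE uterus replicate 2 (-0.45, 0.0903), and within slides the medians were -0.91, -1.07 and 0.29. Adjusted over the list alone, 1 NK marker passed lower, 1 endothelial gene higher and 5 lower, and 0 members of the other described lists passed. Interferon response genes (median 0.47) and hypoxia genes (0.28) were also called higher, and gland markers (-1.38) and intestine and pancreas markers (-0.61) lower, the last 2 without a call once slide was a block (adjusted p = 0.094 and 0.0776). Hypoxia genes lost the call without PRCre uterus replicate 1 (adjusted p = 0.0759) or ERBOE uterus replicate 1 (0.103). Interferon response genes lost the call without PRCre uterus replicate 2 (0.241) or ERBOE uterus replicate 1 (0.192). Intestine and pancreas markers lost the call without PRCre uterus replicate 2 (0.168), PRCre uterus replicate 3 (0.127), ERBOE uterus replicate 1 (0.0553) or ERBOE uterus replicate 3 (0.224). Gland markers lost the call without PRCre uterus replicate 3 (0.655), ERBOE uterus replicate 1 (0.192) or ERBOE uterus replicate 2 (0.0502). The other 22 lists had adjusted p from 0.156 to 0.94.

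The same comparison in eutopic endometrium asks about the genotype in mice that carry a wild-type lesion. Cell-cycle genes again read higher as a group in ERBOE, 47 of 47 with a median of 0.96, and interferon response genes read lower, 28 of 29 with a median of -0.53, neither with a call at an estimated correlation. Ccne1, the gene of cyclin E1, read 2.25 ± 0.74 higher, and the interferon-induced genes Rsad2 and Ifit3 read -1.08 ± 0.59 and -1.56 ± 0.92. No single gene passed in limma, which gave 978 features at an unadjusted p under 0.05, fewer than the 1659 of chance, and a smallest adjusted p of 0.761. That p was shared by all 10 named genes, which did not pass: Khdc1c (3.09 ± 0.53), Clvs2 (-1.94), Zbtb8b (2.23), the fatty acid transport gene Slc27a3 (1.83), Necab2 (2.42), Ntm (2.72), Rflna, which was not well above background in PRCre and at least 5.76-fold higher, and 3 genes that were higher but well above background on 1 of 3 PRCre arrays: Krtap17-1, Adrb1, the beta-1 adrenergic receptor gene, and the ephrin receptor gene Epha8. Without PRCre eutopic replicate 1 the count was 2.

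In eutopic endometrium 10 of 32 lists were called by genotype, 1 higher and 9 lower, and 0 with an estimated correlation (smallest adjusted p = 0.408). Cell-cycle genes had an adjusted p = 7.16e-16 (0.761 with an estimated correlation) and a median of 0.96 with slide as a block, but -0.67 within slide 2 and 2.11 within slide 3, and their call ended without ERBOE eutopic replicate 3 (median 0.19, adjusted p = 0.199). Ttk, a spindle checkpoint kinase gene well above background on 1 of 3 PRCre arrays, read higher. Interferon response genes had an adjusted p = 0.000573 (0.761 with an estimated correlation), with -0.53 as a block median and -0.76 and -0.34 within slides. That call ended without PRCre eutopic replicate 2 (-0.15, adjusted p = 0.486), without PRCre eutopic replicate 3 (-0.15, 0.111) and with no filter on dim probes (-0.53, 0.097). Adjusted over the list alone, 0 members of either list passed. Smooth muscle markers (median -0.29), TNF and NF-kB response genes (-0.31), hypoxia genes (-0.21) and ovary and oviduct markers (-0.33) were also called lower. Epithelial markers (-0.27), endothelial genes (-0.29), immediate-early genes (-0.24) and neural genes (-0.16) were called lower too, without a call once slide was a block (adjusted p = 0.0587 each). Neural genes lost the call without PRCre uterus replicate 1 (adjusted p = 0.0614), PRCre eutopic replicate 1 (0.055), PRCre eutopic replicate 2 (0.118), PRCre eutopic replicate 3 (0.111), ERBOE eutopic replicate 1 (0.124) or ERBOE eutopic replicate 2 (0.113). Endothelial genes lost the call without PRCre eutopic replicate 1 (0.934), ERBOE eutopic replicate 1 (0.536) or ERBOE eutopic replicate 3 (0.0632). Immediate-early genes lost the call without PRCre eutopic replicate 1 (0.148), PRCre eutopic replicate 2 (0.422) or ERBOE eutopic replicate 1 (0.143). Ovary and oviduct markers lost the call without PRCre eutopic replicate 1 (0.0821) or PRCre eutopic replicate 2 (0.118). Smooth muscle markers lost the call without PRCre eutopic replicate 1 (0.934). Epithelial markers lost the call without PRCre eutopic replicate 2 (0.737), PRCre eutopic replicate 3 (0.336), ERBOE eutopic replicate 1 (0.124) or ERBOE eutopic replicate 2 (0.246). Hypoxia genes lost the call without PRCre eutopic replicate 2 (0.26) or ERBOE eutopic replicate 1 (0.134). TNF and NF-kB response genes lost the call without PRCre eutopic replicate 2 (0.156). The other 22 lists had adjusted p from 0.0824 to 0.985.

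In ectopic lesions the comparison asks how ERBOE differs from PRCre in lesion tissue that grows in wild-type hosts. NK and cytotoxic lymphocyte markers read lower in ERBOE lesions, 23 of 24 with a median of -1.34, while adipocyte markers read higher, 22 of 23 with a median of 1.27, as did cell-cycle genes, 46 of 47 with a median of 0.97. None of these 3 lists was called with an estimated correlation. Gzme, the gene of granzyme E, was not well above background in ERBOE lesions and at least 8.12-fold lower. No single gene passed in limma, which gave 1479 features at an unadjusted p under 0.05 and a smallest adjusted p of 0.0775.

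The 10 named genes in lesions, none of which passed, began with Rgs9, a regulator of G protein signalling that read -1.73 ± 0.23 in ERBOE (adjusted p = 0.0775). Chrna1, the muscle acetylcholine receptor subunit gene, was not well above background in PRCre and at least 6.44-fold higher, Zbtb8b read 3.19 ± 0.47, and the zinc finger gene Zfp819 was at least 11.0-fold higher. Clvs2 was not well above background in ERBOE lesions and at least 3.30-fold lower. Tmem229a, well above background on 1 of 3 ERBOE arrays, was lower and the adrenergic receptor gene Adra1d, on 1 of 3 PRCre arrays, higher. Me1, which encodes malic enzyme, read 1.47, Sfrp5, a secreted Wnt inhibitor gene, 1.81, and the neuropeptide gene Adcyap1 was measured on 2 of 3 ERBOE arrays and at least 7.02-fold higher. The count of 0 became 3 without PRCre uterus replicate 1, 1 without PRCre ectopic replicate 1, and 2 with normexp, 1 with trended and robust variance, 1 with the filter on all 18 arrays and 5 with array weights. Rgs9 passed without PRCre uterus replicate 1 (adjusted p = 0.0256), with normexp (0.0314), with trended and robust variance (0.0348), with the filter on all 18 arrays (0.0199) and with array weights (0.0151). Zbtb8b passed without PRCre uterus replicate 1 (0.02), with normexp (0.00112) and with array weights (0.00414), which also passed Zfp819 (0.0161) and Clvs2 (0.038).

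Of 32 lists in lesions 13 were called by genotype, 9 higher and 4 lower, and 0 with an estimated correlation (smallest adjusted p = 0.405). NK markers had an adjusted p = 1.11e-13 (0.405 with an estimated correlation), a block median of -1.34 and -0.64 and -1.62 within slides. The chemokine gene Xcl1 read -1.87 ± 0.55, and the receptor genes Klre1 and Klrk1 -1.82 and -1.42, and 10 NK markers passed lower when adjusted over the list alone. Adipocyte markers had 9.26e-11 (0.405 with an estimated correlation), a block median of 1.34, and 2.12 and 1.04 within slides, with Lipe, the gene of hormone-sensitive lipase, at 1.52, the lipid droplet gene Plin4 at 1.75 and the lipoprotein lipase gene Lpl at 1.27. The adipocyte median ranged from 0.84 to 2.00 over the alternatives. Cell-cycle genes had 1.11e-13 (0.517 with an estimated correlation), a block median of 1.01 and 1.29 and 0.81 within slides, with Ccne1 at 1.60 and Tyms at 1.04. Matrix and EMT genes were higher for 29 of 39 (median 0.27; adjusted p = 3.51e-05; 0.517 with an estimated correlation; block 0.26; within slides -0.01 and 0.39), and Cthrc1 at 1.18 ± 0.26 and the collagen gene Col8a1 at 2.46 ± 0.60 were the 2 members that passed adjusted over the list alone. TNF and NF-kB response genes were higher for 29 of 35 (median 0.42; adjusted p = 0.00154; 0.654 with an estimated correlation; block 0.31; within slides 0.45 and -0.13), with Ccl5 at -2.13 ± 0.88 and Cxcl3, well above background on 1 of 3 PRCre arrays, higher. The TNF call ended without PRCre ectopic replicate 3 (median -0.02, adjusted p = 0.254) and without ERBOE ectopic replicate 1 (-0.06, 0.661). Adjusted over the list alone, 0 adipocyte, cell-cycle or TNF genes passed. B cell markers (-0.82), T cell markers (-0.63) and interferon response genes (-0.66) were called lower, and hypoxia (0.30), erythroid (1.02), complement (0.17), immediate-early (0.31) and neutrophil genes (1.07) higher. Complement genes lost the call without PRCre ectopic replicate 1 (adjusted p = 0.152), PRCre ectopic replicate 3 (0.254) or ERBOE ectopic replicate 1 (0.432). B and plasma cell markers lost the call without PRCre ectopic replicate 2 (0.318). Interferon response genes lost the call without PRCre ectopic replicate 2 (0.219) or PRCre ectopic replicate 3 (0.0658). T cell markers lost the call and turned in direction without PRCre ectopic replicate 2 (0.22, adjusted p = 0.3), and lost it without ERBOE ectopic replicate 2 (0.0505). Neutrophil markers lost the call without PRCre ectopic replicate 3 (0.0521) or ERBOE ectopic replicate 1 (0.432). Immediate-early genes lost the call without ERBOE ectopic replicate 1 (0.432). The other 19 lists had adjusted p from 0.0657 to 0.839.

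Ectopic lesions against eutopic endometrium in ERBOE asks what sets lesion tissue apart from endometrium in place, although the tissues came from different animals, ERBOE fragments in wild-type hosts and ERBOE hosts with a wild-type implant. Genes of fat cells were among those that rose most in the lesions: Fabp4, a fatty acid carrier, by 7.88 ± 1.26 log2 units, the perilipin gene Plin1 by 6.38 ± 0.82 and Adipoq, the gene of the hormone adiponectin, by 8.00 ± 1.54. Of 23 adipocyte markers 23 were higher and 14 passed on their own. Cytokine, macrophage, complement and matrix genes were called higher as groups at the preset correlation but not with an estimated one (adjusted p = 0.143, 0.17, 0.143 and 0.143). The chemokine gene Cxcl3 was not well above background in eutopic endometrium and rose at least 18.1-fold, and the NK receptor gene Klra4 fell by 2.73. In limma 199 features passed, 154 higher and 45 lower, of which 153 had a symbol, among 3522 at an unadjusted p under 0.05.

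The 5 largest increases with groups that did not overlap were Adipoq (adjusted p = 0.0279), the small secreted protein gene Wfdc21 (0.00291; well above background on 1 of 3 eutopic arrays, so its size is left open), Fabp4 (0.0102), the lipid droplet gene Cidec (7.73 ± 1.48; 0.0276) and Car3, a carbonic anhydrase gene (7.44 ± 1.25; 0.0118). The 5 largest decreases were Khdc1a (-5.22 ± 0.87; 0.0115), Nell1 (0.0118; well above background on 1 of 3 lesion arrays), Khdc1c (-3.91 ± 0.53; 0.00379), and Ccdc187 and the glutathione transferase gene Gsta2, both not well above background in lesions and at least 5.15-fold and 2.00-fold lower. With slide as a block Adipoq (adjusted p = 0.051) and Gsta2 (0.0525) missed the threshold, and with normexp Ccdc187 (0.053) and Gsta2 (0.435) did. With the compared arrays alone Adipoq (0.144), Fabp4 (0.106), Cidec (0.138), Car3 (0.106), Khdc1a (0.09), Nell1 (0.11), Ccdc187 (0.177), Plin1 (0.07), Col8a1 (0.18) and Klra4 (0.153) missed it. The median of all features was -0.13. The count was 284 with slide as a block, 119 with the filter on all 18 arrays, 115 with the compared arrays alone and 1256 with array weights. It was 62 without ERBOE ectopic replicate 1, 90 without ERBOE ectopic replicate 3, 132 without ERBOE eutopic replicate 1, 98 without ERBOE eutopic replicate 2 and 66 without ERBOE eutopic replicate 3. Each of these 10 genes except Wfdc21 and Khdc1c missed the threshold without at least 1 of those arrays, where the adjusted p of Adipoq reached 0.149.

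Among 32 lists 19 were called in the ERBOE lesions, 18 higher and 1 lower. Adipocyte markers had a median of 3.66 (adjusted p = 3.72e-35; 0.0155 with an estimated correlation, the 1 list that held; fry adjusted p = 0.000642), with 18 members past adjusted over the list alone, a block median of 4.06 and 3.45 and 3.78 within slides. Lipe rose by 3.07 ± 0.42, Plin4 by 3.81 and Adrb3, the adrenergic receptor of fat cells, by 5.04. TNF and NF-kB response genes were higher for 34 of 35 (median 1.33; adjusted p = 6.52e-17; 0.143 with an estimated correlation; block 1.62; within slides 0.91 and 2.47), where 1 passed over all features and 11 adjusted over the list alone. Ccl3 read 3.74 ± 0.91, Il1b 4.94 ± 1.29, and Il6 was not well above background in eutopic endometrium, measured on 2 of 3 lesion arrays and at least 3.48-fold higher. Macrophage markers were higher for 28 of 30 (median 1.14; 6.04e-15; 0.17 with an estimated correlation; block 1.40; within slides 0.84 and 1.80; 8 past adjusted over the list alone), with the scavenger receptor gene Cd163 at 3.08 and Msr1, well above background on 1 of 3 eutopic arrays, higher. Complement genes were higher for 23 of 24 (median 1.09; 1.7e-13; 0.143 with an estimated correlation; block 1.34; within slides 0.84 and 1.90; 7 past adjusted over the list alone), with Cfd, which is also a fat cell product and an adipocyte marker here, at 7.64 ± 1.64 (adjusted p = 0.0526) and C4a at 2.43. Matrix and EMT genes were higher for 33 of 39 (median 0.62; 5.69e-11; 0.143 with an estimated correlation; block 0.55; within slides 0.91 and 0.69; 10 higher and 1 lower past adjusted over the list alone). Col8a1 rose by 3.34 ± 0.60 (adjusted p = 0.0176), and Timp1, Tgfb3 and Tnc read 2.80, 1.27 and 2.49. NK markers were lower for 20 of 24 (median -1.17; 7.94e-06; 0.246 with an estimated correlation; block -1.35; within slides -1.25 and -1.98; 9 past adjusted over the list alone), with Klra4 (adjusted p = 0.0176), Klra8 at -2.62, Klra9 at -1.44 and Styk1 at -1.98. The calls of Cxcl3, Col8a1 and Klra4 each ended without ERBOE ectopic replicate 1, at adjusted p of 0.0637, 0.102 and 0.09. B cell (1.01), endothelial (0.55), hypoxia (0.60), neutrophil (0.83), immediate-early (0.59), neural (0.33), T cell (0.52), mast cell and eosinophil (0.54), interferon (0.28) and inflammasome (0.13) lists were called higher too. Cell-cycle (0.65), oestrogen-induced (0.43) and apoptosis genes (0.08) were called higher without a call once slide was a block (adjusted p = 0.0681, 0.105 and 0.0649). Inflammasome genes lost the call without ERBOE ectopic replicate 1 (adjusted p = 0.0973) or ERBOE eutopic replicate 2 (0.118). Interferon response genes lost the call without ERBOE ectopic replicate 1 (0.0902) or ERBOE eutopic replicate 3 (0.216). Oestrogen-induced uterine genes lost the call without ERBOE ectopic replicate 1 (0.0902) or ERBOE eutopic replicate 2 (0.268). Apoptosis genes lost the call without ERBOE ectopic replicate 2 (0.0509), ERBOE eutopic replicate 1 (0.0719) or ERBOE eutopic replicate 2 (0.0738). T cell markers lost the call without ERBOE ectopic replicate 3 (0.0885). Cell-cycle genes lost the call without ERBOE eutopic replicate 1 (0.179). Over the alternatives the adjusted p reached 0.138 for mast cell and eosinophil markers and 0.0577 for both immediate-early and neural genes, so these calls did not always hold either. The other 13 lists had adjusted p from 0.103 to 0.99.

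**Figure D2:**
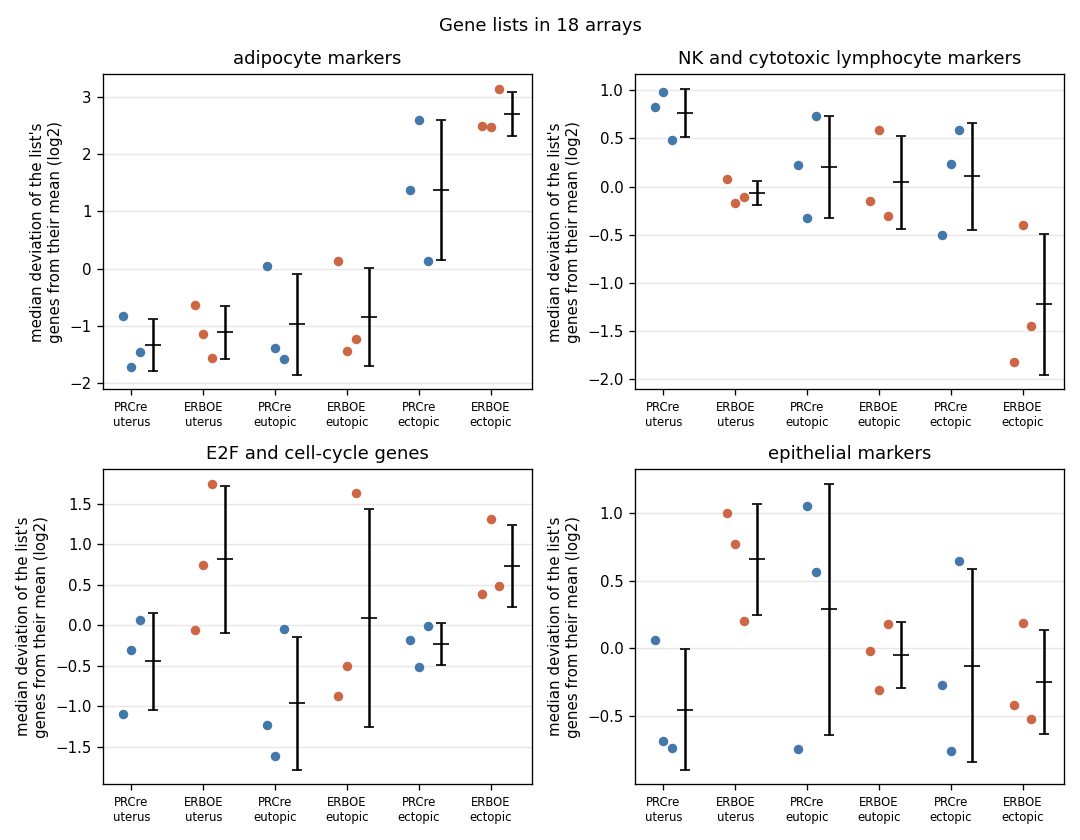
Median deviation, in log2 units, of the members of 4 gene lists (adipocyte, NK and cytotoxic lymphocyte, E2F and cell-cycle, epithelial) from each gene's mean over the 18 arrays, with 1 point per array, and a bar for the mean and SD of each of the 6 groups of 3 arrays. Adipocyte scores are highest in the lesions of both genotypes, and NK scores are lower in ERBOE lesions (mean -1.23) than in PRCre lesions (0.11).

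In PRCre mice the same lesion against eutopic comparison was led by Grem1, which encodes a secreted antagonist of bone morphogenetic proteins. Grem1 was measured on 3 of 3 lesion arrays, was not well above background in eutopic endometrium and rose at least 7.64-fold (adjusted p = 0.00248), and was higher within the 1 slide that held both groups. Fat cell and B cell markers were higher as groups, by medians of 2.62 and 1.90, and macrophage and T cell markers by 1.09 and 1.32, while genes of ciliated cells were lower by a median of -0.88. The latter 3 lists were not called with an estimated correlation, and PRCre ectopic replicate 2 carried much of the T cell signal, with the list's median deviation on an array at 2.51 there and 0.46 and -0.04 on the other PRCre lesion arrays. Without that array the T cell median was 0.39 and the macrophage median 0.48, both still called. The B cell median ranged from 0.94 with normexp to 2.34 over the alternatives and was 1.17 without PRCre eutopic replicate 3, still called. Grem1 was the 1 feature past the threshold in limma, among 1303 at an unadjusted p under 0.05. In ERBOE mice Grem1, looked up after its values were seen, was also higher in lesions (adjusted p = 2.51e-05), by an amount left open because its eutopic signals lay no higher there than in PRCre. The count was 50 without PRCre ectopic replicate 3, 10 without PRCre eutopic replicate 1, and 3 without PRCre ectopic replicate 1, PRCre ectopic replicate 2 or PRCre eutopic replicate 2. It was 7 with normexp, 4 with trended and robust variance, 26 with array weights, and 0 with the filter on all 18 arrays or with the compared arrays alone, and Grem1 missed with normexp (adjusted p = 0.0585) and with the compared arrays alone (0.56).

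In PRCre mice 17 of 32 lists were called in lesions, 13 higher and 4 lower, and 2 of them held with an estimated correlation. Adipocyte markers were higher for 17 of 23 (adjusted p = 3.16e-22; 0.0458 with an estimated correlation; fry adjusted p = 0.0624; block 2.63; within slide 2 3.76), and 14 passed adjusted over the list alone, with Plin1 at 4.44 ± 0.82, Lpl at 2.62, Acsl1 at 2.81 and Fabp4 at 5.63. B cell markers were higher for 19 of 20 (adjusted p = 3.16e-22; 0.0458 with an estimated correlation; fry adjusted p = 0.0624; block 1.97; within slide 2 2.79), and 9 passed adjusted over the list alone. Fcmr, a receptor gene for IgM, was higher and well above background on 1 of 3 eutopic arrays, and Ms4a1 and Cxcr5 were not well above background in eutopic endometrium and at least 14.1-fold and 3.70-fold higher. Macrophage markers were higher for 30 of 30 (adjusted p = 3.46e-20; 0.156 with an estimated correlation; block 1.48; within slide 2 1.86; 2 past adjusted over the list alone), with Marco at 4.05 ± 0.98 and Msr1 not well above background in eutopic endometrium and at least 3.71-fold higher. Ciliated cell markers were lower for 13 of 15 (adjusted p = 4.69e-07; 0.14 with an estimated correlation; block -0.62; within slide 2 -0.33; 2 past adjusted over the list alone), with the ciliogenesis regulator Foxj1 not well above background in lesions and at least 4.36-fold lower, and Rsph1 at -1.09. T cell (1.32), complement (0.78), TNF and NF-kB (0.65), matrix (0.34), inflammasome (0.34), neutrophil (0.30), endothelial (0.28), apoptosis (0.07) and interferon genes (0.36, but -0.32 within slide 2) were called higher as well, and smooth muscle (-0.47), epithelial (-0.40) and gland markers (-1.49) lower. Cell-cycle genes (0.80) were called higher without a call once slide was a block (0.27, adjusted p = 0.0581), with -0.23 within slide 2. Smooth muscle markers lost the call without PRCre ectopic replicate 1 (adjusted p = 0.236) or PRCre eutopic replicate 1 (0.448). Apoptosis genes lost the call without PRCre ectopic replicate 2 (0.257), PRCre ectopic replicate 3 (0.196), PRCre eutopic replicate 1 (0.904) or PRCre eutopic replicate 3 (0.0626). Epithelial markers lost the call without PRCre ectopic replicate 2 (0.406), PRCre eutopic replicate 2 (0.781) or PRCre eutopic replicate 3 (0.0787). Gland markers lost the call without PRCre ectopic replicate 2 (0.262), PRCre ectopic replicate 3 (0.169) or PRCre eutopic replicate 1 (0.51). Inflammasome genes lost the call without PRCre ectopic replicate 2 (0.0732) or PRCre eutopic replicate 1 (0.131). Interferon response genes lost the call without PRCre ectopic replicate 2 (0.18), PRCre ectopic replicate 3 (0.138) or PRCre eutopic replicate 1 (0.51). Endothelial genes lost the call without PRCre ectopic replicate 3 (0.131) or PRCre eutopic replicate 3 (0.271). Neutrophil markers lost the call without PRCre eutopic replicate 1 (0.0709). TNF and NF-kB response genes lost the call without PRCre eutopic replicate 1 (0.0613). The other 15 lists had adjusted p from 0.217 to 0.889.

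Eutopic endometrium against uterus sets the endometrium of mice with a wild-type implant beside the uterus of mice without surgery. Dissection of the 2 tissues may differ and surgery does, so a difference cannot be credited to lesions alone. In PRCre mice epithelial markers read higher in eutopic endometrium, 26 of 28 with a median of 0.76, with the ligand gene Wnt7b at 1.98 ± 0.69 and Cdh1 at 1.53 ± 0.56. In ERBOE mice they read lower, 24 of 28 with a median of -0.63, as did 39 of 47 cell-cycle genes with a median of -0.53, though no list was called with an estimated correlation (smallest adjusted p = 0.953 in PRCre and 0.772 in ERBOE) and the ERBOE cell-cycle call ended with slide as a block. The mitotic motor gene Kif11 read -2.29 ± 0.77 and Ube2c -1.87 ± 0.80 in ERBOE. No gene passed in limma in either genotype, which gave 2211 features at an unadjusted p under 0.05 in PRCre and 1108 in ERBOE, with smallest adjusted p of 0.747 and 0.767. In PRCre the count became 2 without PRCre uterus replicate 1, 1 without PRCre uterus replicate 2, 1 without PRCre eutopic replicate 1 and 1 with normexp.

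Of 32 lists 6 were called for eutopic endometrium against uterus in PRCre mice (4 higher, 2 lower) and 8 in ERBOE mice (3 higher, 5 lower), and 0 in either with an estimated correlation. Epithelial markers in PRCre had an adjusted p = 1.22e-06 (0.953 with an estimated correlation), a block median of 0.76, and 1.33 and -0.01 within slides. In ERBOE they had 3.05e-07 (0.772 with an estimated correlation), a block median of -0.59, and -0.64 and -1.07 within slides. Cell-cycle genes in ERBOE had 7.49e-08 (0.898 with an estimated correlation), but -1.44 in slide 2 and 0.71 in slide 3, and their call ended with slide as a block (-0.19, adjusted p = 0.0948), without ERBOE uterus replicate 3 (-0.03, 0.522) and without ERBOE eutopic replicate 1 (-0.12, 0.25). Adjusted over the list alone, 0 members of these lists passed. In PRCre, interferon (0.56), adipocyte (0.69) and hypoxia genes (0.29) were also called higher, and NK markers (-0.56) and cell-cycle genes (-0.46) lower, the last 2 without a call once slide was a block (-0.34, adjusted p = 0.465, and -0.08, adjusted p = 0.765). In ERBOE, gland (1.05), progesterone-induced (0.66) and intestine and pancreas markers (0.46) were called higher, and interferon (-0.48), oestrogen-induced (-0.67) and hypoxia genes (-0.27) lower, with the intestine call lost once slide was a block (adjusted p = 0.12). In PRCre, hypoxia genes lost the call without PRCre uterus replicate 1 (adjusted p = 0.159), PRCre uterus replicate 2 (0.0769) or PRCre eutopic replicate 2 (0.593). Adipocyte markers lost the call without PRCre uterus replicate 2 (0.0788) or PRCre eutopic replicate 1 (0.0987). E2F and cell-cycle genes lost the call without PRCre uterus replicate 2 (0.12), PRCre uterus replicate 3 (0.981), PRCre eutopic replicate 1 (0.476) or PRCre eutopic replicate 2 (0.515). Interferon response genes lost the call without PRCre uterus replicate 2 (0.416), PRCre eutopic replicate 2 (0.468) or PRCre eutopic replicate 3 (0.137). NK markers lost the call without PRCre uterus replicate 2 (0.12), PRCre eutopic replicate 1 (0.0987) or PRCre eutopic replicate 2 (0.122). In ERBOE, gland markers lost the call without ERBOE uterus replicate 1 (adjusted p = 0.139) or ERBOE eutopic replicate 2 (0.36). Hypoxia genes lost the call without ERBOE uterus replicate 1 (0.0724) or ERBOE eutopic replicate 1 (0.06). Interferon response genes lost the call without ERBOE uterus replicate 1 (0.139). Progesterone-induced uterine genes lost the call without ERBOE uterus replicate 1 (0.121) or ERBOE eutopic replicate 2 (0.873). Intestine and pancreas markers lost the call without ERBOE uterus replicate 3 (0.335), ERBOE eutopic replicate 2 (0.0695) or ERBOE eutopic replicate 3 (0.0598). Oestrogen-induced uterine genes lost the call without ERBOE eutopic replicate 2 (0.0778). The other lists had adjusted p from 0.0737 to 0.946 in PRCre and from 0.0575 to 0.997 in ERBOE.

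Genotype effects were set side by side across tissues to ask whether ERBOE changes the same genes in each. Across 33180 features the log2 differences correlated at 0.315 (Spearman 0.330) between eutopic endometrium and lesions, at 0.10 (0.107) between uterus and eutopic endometrium and at -0.03 (0.02) between uterus and lesions. Jackknife standard errors over the 18 arrays were 0.166, 0.319 and 0.207. The genotype effects in uterus and eutopic endometrium correlated at -0.0453 without PRCre eutopic replicate 1, -0.0276 without PRCre uterus replicate 1, -0.0394 without ERBOE uterus replicate 3 and -0.0339 without ERBOE eutopic replicate 3. Those in uterus and lesions correlated at 0.0974 without PRCre ectopic replicate 3, 0.0332 without PRCre uterus replicate 3, 0.0309 without ERBOE uterus replicate 1 and 0.0045 without ERBOE ectopic replicate 2, so neither sign held over the arrays. With slide as a block the 3 correlations were 0.343, 0.10 and -0.026. Among features at an unadjusted p under 0.05, 79 were higher and 57 lower in both eutopic endometrium and lesions, against 12.1 and 9.38 by chance. For uterus and eutopic endometrium these counts were 69 and 59 against 24.9 and 22.1, and for uterus and lesions 45 and 71 against 28.9 and 45.0. With no filter on dim probes the eutopic and lesion effects correlated at 0.0203, and with the filter on all 18 arrays at 0.494. In the tests of the difference itself, 0 genes passed in limma for lesions minus eutopic (547 at an unadjusted p under 0.05), lesions minus uterus (2238) and eutopic minus uterus (1692), so no single gene was shown to respond differently between tissues. The lesion minus uterus count became 1 without PRCre ectopic replicate 3.

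A contrast of ERBOE against PRCre averaged over the 3 tissues, 9 arrays a side, was chosen after seeing the data. Zbtb8b, a zinc finger gene, rose by 2.53 ± 0.27 (adjusted p = 0.00271), with 9 of 9 ERBOE arrays above all PRCre arrays, although it was well above background on only 1 or 2 of 3 arrays of each PRCre group. Clvs2 was lower (adjusted p = 0.000974), with 8 of 9 ERBOE arrays below all PRCre arrays, by an amount left open because 0 of 3 ERBOE lesion arrays were well above background. Tmem229a, well above background on 1 of 3 ERBOE lesion arrays, was lower (0.0434) with 5 of 9, and Rgs9 fell by 0.95 ± 0.13 (0.0434) with 3 of 9. These were the 4 features past the threshold in limma among 2988 at an unadjusted p under 0.05, and Rgs9 in the uterus had group means of -0.39 in ERBOE and -0.33 in PRCre. Within slides the Clvs2 difference ran from -2.99 to -1.79 in uterus and eutopic endometrium and that of Zbtb8b from 1.56 to 3.39 over the 7 slide and tissue pairs. With slide as a block 3 features passed, 1 higher and 2 lower. The count was 2 without PRCre uterus replicate 3, any 1 of the ERBOE uterus arrays, ERBOE ectopic replicate 1, ERBOE eutopic replicate 1 or ERBOE eutopic replicate 3, and rose to 7, 8, 9 and 16 without PRCre uterus replicate 1, PRCre uterus replicate 2, PRCre eutopic replicate 1 and ERBOE eutopic replicate 2.

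**Figure D3:**
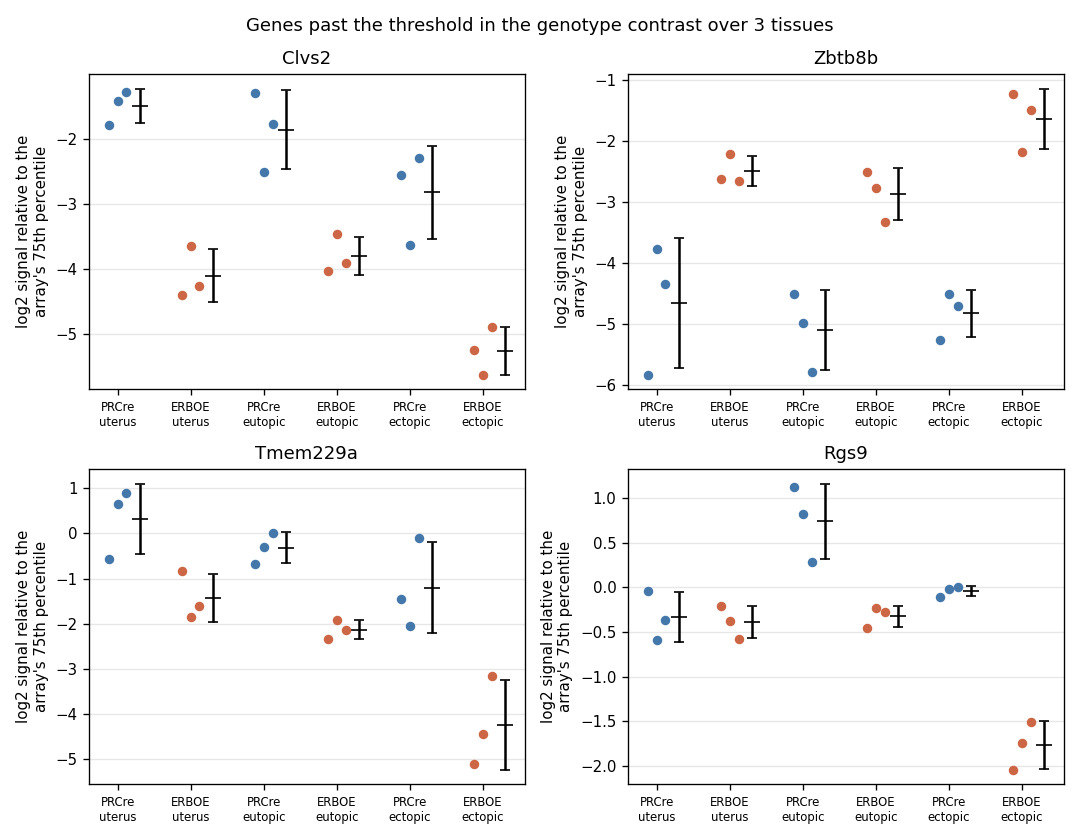
Log2 signal relative to the array's 75th percentile of Clvs2, Zbtb8b, Tmem229a and Rgs9, with 1 point per array, and a bar for the mean and SD of each of the 6 groups of 3 arrays. Clvs2 is lower in ERBOE in uterus (-4.11 against -1.50) and eutopic endometrium (-3.80 against -1.86) and not well above background in ERBOE lesions, and Zbtb8b is higher in ERBOE in all 3 tissues.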

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

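Tests of the difference between genotype effects in 2 tissues picked out 31 results on gene lists, and those tests were planned. The tests of slide, leukocyte share, the Klr gene cluster, linkage and adipose tissue, the pooled contrasts, the count of features shared by 3 tissues, and the 3 patterns weighed here were chosen after related results were seen.

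At the preset correlation fat cell markers were called further up, and NK markers further down, with ERBOE in lesions than in eutopic endometrium. With an estimated correlation neither was called (adjusted p = 0.174 and 0.276), nor any other list, and 30 of 100 splits called as many lists. The genotype effect in lesions minus that in eutopic endometrium had a median of 1.92 log2 units for adipocyte markers and -1.33 for NK and cytotoxic lymphocyte markers. Over the alternatives the former ranged from 0.97 without PRCre eutopic replicate 1 to 2.43, with 1.04 without ERBOE eutopic replicate 3, and the latter from -1.94 to -0.71 with normexp. It was also called higher for TNF and NF-kB response genes (0.92), immediate-early genes (0.66), eosinophil and mast cell markers (0.66), hypoxia genes (0.59), complement genes (0.43), neural genes (0.32), endothelial genes (0.30), matrix and EMT genes (0.26), ciliated cell markers (0.23), epithelial markers (0.16) and mesothelial markers (0.12), and lower for T cell markers (-0.70) and B and plasma cell markers (-0.47). With slide as a block epithelial markers lost the call (adjusted p = 0.105). Ciliated cell markers lost the call without PRCre ectopic replicate 1 (adjusted p = 0.0715), PRCre eutopic replicate 2 (0.861), ERBOE ectopic replicate 3 (0.0578) or ERBOE eutopic replicate 2 (0.0652). Epithelial markers lost the call without PRCre ectopic replicate 1 (0.0715), PRCre ectopic replicate 2 (0.835), PRCre eutopic replicate 2 (0.861), PRCre eutopic replicate 3 (0.277), ERBOE ectopic replicate 2 (0.648), ERBOE eutopic replicate 1 (0.0588) or ERBOE eutopic replicate 2 (0.145). B and plasma cell markers lost the call without PRCre ectopic replicate 2 (0.835), PRCre eutopic replicate 3 (0.31), ERBOE ectopic replicate 2 (0.574) or ERBOE eutopic replicate 1 (0.176). T cell markers lost the call without PRCre ectopic replicate 2 (0.391) or ERBOE ectopic replicate 2 (0.0659). Complement genes lost the call without PRCre ectopic replicate 3 (0.069), PRCre eutopic replicate 2 (0.0786) or ERBOE ectopic replicate 1 (0.112). Eosinophil and mast cell markers lost the call without PRCre ectopic replicate 3 (0.145). Mesothelial markers lost the call without PRCre ectopic replicate 3 (0.669), PRCre eutopic replicate 1 (0.0622), PRCre eutopic replicate 2 (0.0786), ERBOE ectopic replicate 3 (0.229) or ERBOE eutopic replicate 2 (0.292). Endothelial genes lost the call without PRCre eutopic replicate 1 (0.114). TNF and NF-kB response genes lost the call without PRCre eutopic replicate 2 (0.0647). Over the alternatives the adjusted p reached 0.215 for neural genes, 0.294 for matrix and EMT genes and 0.14 for immediate-early genes, so these calls did not always hold either. The other 17 lists had adjusted p from 0.0572 to 0.99.

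Against the uterus, the genotype effect in lesions was higher for gland markers (2.73), eosinophil and mast cell markers (1.75), erythroid markers (1.56), adipocyte markers (1.1), endothelial genes (0.53), matrix and EMT genes (0.49) and neural genes (0.49). It was lower for epithelial markers (-1.14), interferon response genes (-1.13) and NK markers (-0.61). These are calls at the preset correlation, and none of the lists was called with an estimated one. Neural genes lost the call without PRCre uterus replicate 1 (adjusted p = 0.052), PRCre uterus replicate 2 (0.0528), PRCre uterus replicate 3 (0.0789), ERBOE uterus replicate 3 (0.108), PRCre ectopic replicate 1 (0.0746), ERBOE ectopic replicate 1 (0.161) or ERBOE ectopic replicate 3 (0.0912). Erythroid markers lost the call without PRCre uterus replicate 2 (0.0907). Endothelial genes lost the call without PRCre uterus replicate 3 (0.159). Gland markers lost the call without PRCre uterus replicate 3 (0.111). Matrix and EMT genes lost the call without PRCre uterus replicate 3 (0.0536). NK and cytotoxic lymphocyte markers lost the call without PRCre uterus replicate 3 (0.107), ERBOE uterus replicate 3 (0.0649), PRCre ectopic replicate 2 (0.0806), PRCre ectopic replicate 3 (0.226), ERBOE ectopic replicate 1 (0.508) or ERBOE ectopic replicate 3 (0.119). Adipocyte markers lost the call without PRCre ectopic replicate 3 (0.0946). The other 22 lists had adjusted p from 0.055 to 0.931, and the smallest with an estimated correlation was 0.4.

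In eutopic endometrium the genotype effect was higher than in the uterus for gland markers (2.18) and lower for epithelial markers (-1.42), oestrogen-induced genes (-0.997), interferon response genes (-0.96), hypoxia genes (-0.55) and smooth muscle markers (-0.28). These too are calls at the preset correlation, and none held with an estimated one. Smooth muscle markers lost the call without PRCre uterus replicate 1 (adjusted p = 0.292), ERBOE uterus replicate 2 (0.062) or PRCre eutopic replicate 1 (0.536). Gland markers lost the call without PRCre uterus replicate 3 (0.137) or ERBOE eutopic replicate 2 (0.108). Hypoxia genes lost the call without PRCre eutopic replicate 2 (0.107). Oestrogen-induced uterine genes lost the call without PRCre eutopic replicate 2 (0.11). The other 26 lists had adjusted p from 0.0571 to 0.952, and the smallest with an estimated correlation was 0.612. Regrouping the arrays cannot exclude chance for any of these 3 tests. For lesions minus eutopic endometrium 15 lists were called, 30 of 100 splits called as many, and the highest other split called 22. For lesions minus uterus 10 lists were called, 55 of 100 splits called as many, and the highest other called 20. For eutopic endometrium minus uterus 6 were called, 79 of 100 called as many, and the highest other called 17. Single genes gave 0 in each test, as in limma above, so 100 of 100 splits gave as many, with highest others of 1, 4 and 1. These splits took no account of the replicate numbers.

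NK markers were lower in ERBOE lesions, by a median of -1.34. Slide is argued against, since the list was still called with slide as a block (median -1.34, adjusted p = 1.53e-10) and was lower within both slides (-0.64 and -1.62), although an estimated correlation left it without a call (0.405). Sequence variants in the cluster of neighbouring Klr genes are argued against, since 14 of 15 members outside it were lower, with a median of -1.48. A lower share of all leukocytes stays open, since the macrophage list minus the NK list differed by 1.34 with a 95% interval of -1.60 to 4.28, while neutrophil markers differed by 0.89 and T cell markers by -0.66. The 10 splits of the 6 arrays are too few to exclude chance (real -1.34, highest other 1.65 in size, 2 splits as large), and fewer NK cells in ERBOE lesions may be a biological explanation that was not tested otherwise.

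Features that differed in the same direction at an unadjusted p under 0.05 in uterus, eutopic endometrium and lesions numbered 27, against 1.04 expected of independent lists, among them Inhba (3.31, 1.66 and 2.06), Il33 (1.55, 1.61 and 1.26), Serpinb11 (2.91, 3.68 and 2.83) and Pla2g5 (1.76, 2.52 and 2.01). The splits make chance less likely without excluding it, since the count was chosen after seeing the data and another split gave more. With the real split included, 2 of 100 were as large (real 27, highest other 46). Among splits that part the uterus arrays of the same number 2 of 100 were as large (highest other 33). Slide is argued against, since 48 such features were found with slide as a block, against 2.79 expected of independent lists, and 44 with the replicate block. DNA linked to 1 engineered site is argued against as the source of most of the 15 named genes. At most 3 of them lay on 1 chromosome, where random draws gave a median of 3 and a 95th percentile of 4. The test counted whole chromosomes, so it cannot exclude linked DNA for a few genes, such as Pla2g5, Rap1gap and Zbtb8b, all on chromosome 4. The count was 42 without ERBOE uterus replicate 1, 17 without ERBOE uterus replicate 3 and 16 without ERBOE eutopic replicate 3. A shared response to the receptor may explain it, as a hypothesis found on the same data. That response was not told apart from DNA differences at several sites.

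Adipocyte markers were higher in lesions than in eutopic endometrium over both genotypes, by a median of 2.98, with 16 of 23 past the threshold. The splits argue against chance, since of 100 only the real one was as large (real 2.98, highest other 2.85), though the pooled contrast was chosen after seeing the data. Of 80 splits that part PRCre arrays of the same number, a pairing read from the data, only the real one was as large (highest other 2.52). Slide is argued against, with block medians of 4.06 in ERBOE and 2.63 in PRCre. Adipose tissue in the lesion samples stays open: 95.7% of the markers were higher, with Adipoq at 6.80, Plin1 at 5.41 and Cidec at 6.61, but Lep, the leptin gene, was not higher (-0.05 ± 0.19, adjusted p = 0.938). The 1 probe of Lep was flat over all 6 groups (-2.44 to -2.10), as were the brightest probes of Aqp7 and Lgals12 while their dimmer probes rose, so Lep may be missed by its probe. Fat attached to the dissected samples could explain the other markers, unevenly between pools, since Adipoq was at 0.79 in PRCre eutopic replicate 1 and 0.53 in ERBOE eutopic replicate 1 beside -5.80 to -3.44 on the other 4 eutopic arrays, and a change of cell state in the lesions was not tested against it.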

How the results depend on the processing

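The runs without PRCre uterus replicate 1 beyond its own comparisons, and the pooled contrasts, were chosen after seeing the data. With each array left out a group keeps 2 arrays. The cause was not tested for any change given here, except that fewer features are tested with the filter on all 18 arrays and fewer arrays enter the fit of the compared arrays alone.

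Over the alternatives, named genes kept their direction and their side of the threshold in 2176 planned and 94 added cases, passed only under the alternative in 56 and 3, and lost the call in 60. Direction reversed in 29, all of them Esr2, Esr1 or Pgr, which passed in no comparison. Lists called in the main analysis kept their call in 1943 and 81 cases, and lost it in 282 and 1. The direction of the camera test reversed in 13, which the sign of a list's median given here need not follow, and lists not called in the main analysis were not followed.

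With normexp the genes past the threshold numbered 2 for genotype in lesions, 7 for lesions against eutopic endometrium in PRCre and 1 for eutopic endometrium against uterus in PRCre. Reversed values were 0.011 for Esr1 in eutopic endometrium against uterus in PRCre, and in ERBOE 0.051 for Esr2 and 0.031 for Esr1. Quantile normalisation gave 0.061 for Esr2 and 0.058 for Esr1 in that ERBOE comparison, and the mean of all probes gave 0.002 for Pgr there. The correlation of genotype effects in eutopic endometrium and lesions was 0.0203 with no filter and 0.494 with the filter on all 18 arrays. That filter left 1 gene for genotype in lesions, 0 for lesions against eutopic endometrium in PRCre (limma, where 1303 features had an unadjusted p under 0.05 in the main analysis) and 119 in ERBOE, and turned the test of gland markers in the PRCre comparison (median -0.64).

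The replicate block ended no call of a named gene or list and moved the count of features shared by 3 tissues from 27 to 44. With slide as a block Pgr was 0.026 for genotype in lesions, Esr2 -0.051 for lesions against eutopic endometrium in PRCre, and Esr1 0.034 for eutopic endometrium against uterus in PRCre. In ERBOE the latter comparison gave 0.069 for Esr1 and 0.23 for Pgr, and in PRCre the test of cell-cycle genes turned (median -0.079). Trended and robust variance gave 1 gene for genotype in lesions and 4 for PRCre lesions against eutopic endometrium. Array weights gave 9 genes for genotype in the uterus, 5 in lesions, 26 for lesions against eutopic endometrium in PRCre and 1256 in ERBOE, with Pgr at 0.028 for genotype in lesions and interferon genes at -0.18 for the PRCre lesion comparison. The compared arrays alone gave 0 and 115 genes for the PRCre and ERBOE lesion comparisons.

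Leaving out each array gave 0 to 3 genes for genotype in the uterus, 0 to 2 in eutopic endometrium and 0 to 3 in lesions. It gave 1 to 50 for lesions against eutopic endometrium in PRCre and 62 to 246 in ERBOE, 0 to 2 for eutopic endometrium against uterus in PRCre, and 0 to 1 for the genotype effect in lesions minus uterus. For genotype, Pgr ranged from -0.95 to 0.11 in the uterus and -0.72 to 0.35 in lesions, Esr1 from -0.16 to 0.26 in eutopic endometrium and -0.63 to 0.13 in lesions, and Esr2 from -0.14 to 0.16 in eutopic endometrium. For PRCre lesions against eutopic endometrium Esr2 ranged from -0.12 to 0.12, Esr1 from -0.73 to 0.037 and Pgr from -0.88 to 0.19. For eutopic endometrium against uterus Esr1 ranged from -0.25 to 0.18 in PRCre and -0.13 to 0.08 in ERBOE, and Esr2 from -0.16 to 0.13 in ERBOE. Among lists, genotype in eutopic endometrium ranged from -0.86 to 0.10 for epithelial markers, -0.47 to 0.15 for hypoxia genes and -1.01 to 0.22 for TNF genes, and genotype in lesions from -1.29 to 0.22 for T cell markers. Interferon genes ranged from -0.35 to 0.83 in PRCre lesions against eutopic endometrium. In PRCre eutopic endometrium against uterus, cell-cycle genes ranged from -0.90 to -0.13 and hypoxia genes from -0.014 to 0.7. The genotype effect in lesions minus eutopic endometrium ranged from -0.94 to 0.037 for B cell markers, -0.23 to 0.82 for epithelial markers and -1.26 to 0.29 for T cell markers.

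The median of all features was -0.11 for genotype in the uterus, -0.20 with normexp and -0.27 with no filter, and -0.13 for ERBOE lesions against eutopic endometrium, 0.04 with normexp. Of genes past the threshold in that ERBOE comparison 77.4% were higher, 87.5% with normexp and 56.6% with array weights. PRCre uterus replicate 1 had the lowest signal, at a 75th percentile of 239.6, which limits values near background in its group.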

Other observations

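Contrasts pooled over both genotypes, chosen after seeing the data together with the genes named from them, set 6 lesion arrays against 6 eutopic or 6 uterus arrays. In lesions Clec4d, a receptor gene of myeloid cells, was higher than in eutopic endometrium by 5.50 ± 0.71. The receptor gene Clec4e (adjusted p = 0.0015) and the acute-phase gene Orm1 (0.00069) were higher too, by amounts left open because their eutopic signals were near background, each of the 3 on 6 of 6 arrays. Foxa2, a transcription factor of uterine glands, was lower (adjusted p = 0.00701; 5 of 6 arrays below all eutopic arrays), with PRCre lesion signals near background, and Xpnpep2, an aminopeptidase gene, fell by 2.42 ± 0.29 (0.00114; 6 of 6). In limma 411 features passed, 309 higher and 102 lower, and 388 with slide as a block. The count was 237 without PRCre ectopic replicate 2, 714 without PRCre ectopic replicate 3, 212 without ERBOE ectopic replicate 1, 267 without ERBOE eutopic replicate 2 and 236 without ERBOE eutopic replicate 3. The splits within genotype argue against chance without excluding it (2 of 100 as large with the real one included, real 411, highest other 430). The highest other regrouped only 2 arrays. Among the 80 splits that part the PRCre arrays of the same number only the real one gave as many, and the highest other gave 5, though that pairing was read from the data.

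Against the uterus, 693 features passed in lesions in limma, 471 higher and 222 lower, and 801 with slide as a block. The count was 454 without ERBOE uterus replicate 1, 388 without ERBOE uterus replicate 2, 392, 368 and 1270 without PRCre ectopic replicates 1, 2 and 3, 353 without ERBOE ectopic replicate 1 and 421 without ERBOE ectopic replicate 3. Cyp2e1, a cytochrome P450 gene, rose by 7.02 ± 0.83 (adjusted p = 0.000576). Its means ranked the 6 groups as those of Adipoq did, from -3.85 in ERBOE uterus to 3.86 in ERBOE lesions (Adipoq -4.70 and 4.96). Adipose tissue in the samples thus stays open for it too.

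Over the 3 tissues cell-cycle genes were higher in ERBOE for 47 of 47 members (median 1.1; adjusted p = 2.05e-31; 0.671 with an estimated correlation) and NK markers lower for 24 of 24 (median -0.79; 4.42e-09; 0.671 with an estimated correlation). For the 4 genes past the threshold for ERBOE against PRCre over the 3 tissues the splits make chance less likely without excluding it. With the real split included, 2 of 100 were as large (real 4, highest other 20). The split that called 20 genes, several times the real count, may point to a structure of the samples, though what that split follows was not tested. Among 100 splits that part the uterus arrays of the same number the real one alone gave 4, and the highest other gave 2. Another set of 100 drawn splits also kept each pooled share under 0.05 but gave other highest values.

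For each comparison of 3 arrays against 3 the 10 splits are too few to exclude chance. In genes, the real count and highest other were 0 and 0 for genotype in the uterus and in eutopic endometrium, 0 and 1 in lesions, 1 and 8 for lesions against eutopic endometrium in PRCre (4 splits as large), 199 and 1 in ERBOE, 0 and 0 for eutopic endometrium against uterus in PRCre and 0 and 1 in ERBOE. These zeros are limma counts, beside 3280, 978, 1479, 2211 and 1108 features at an unadjusted p under 0.05, and 10 of 10 splits gave at least as many. In lists called, the real count and highest other were 10 and 11 for genotype in the uterus, 10 and 18 in eutopic endometrium (9 splits as large), 13 and 17 in lesions (3 splits as large), 17 and 19 for PRCre lesions, 19 and 18 for ERBOE lesions, 6 and 17 for eutopic endometrium against uterus in PRCre and 8 and 11 in ERBOE (6 splits as large). For genotype in eutopic endometrium, splits that follow the slides called up to 14 lists, and with slide as a block the real split called 6. A slide-following split called 13 lists for eutopic endometrium against uterus in PRCre, where the block left 4, and 1 gene for genotype in lesions, where the block left 0 (limma, 1948 features at an unadjusted p under 0.05).

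For genotype in the uterus, where the replicate numbers pair the arrays, the split that called 11 lists did not part the 3 pairs. The 3 other splits that part them called 4, 3 and 7 lists, with 916, 690 and 799 features at an unadjusted p under 0.05, against 10 lists and 3280 features for the real split. For PRCre lesions against eutopic endometrium the 3 other splits that part the numbers called 13, 10 and 11 lists and at most 1 gene, against 17 lists and 1 gene for the real split, and the split with 8 genes did not part them.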
